A study of Homo sapiens with 15 samples.

How the data were processed

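Gene-level read counts were deposited in 2 tables, one for 6 MCF7 libraries and one for 9 MCF10A libraries. Per the labels' protocols, total RNA was extracted with RNeasy columns from cells seeded 2 days earlier, samples had an RNA integrity number of at least 7, and 1000 ng went into a NEBNext Ultra II Directional library sequenced on a NovaSeq X Plus. MCF7 cells grew in 10% fetal bovine serum, and MCF10A cells in 5% horse serum with 20 ng/ml EGF, 100 ng/ml cholera toxin and 10 µg/ml insulin. Per the submitters' processing notes, the authors used FastQC, aligned reads with STAR to hg38/GRCh38 and counted them per gene with featureCounts, with no versions or settings given. The deposited values are raw counts, whole numbers that were not normalised. The strand setting of the counting was not stated, so counts of antisense and overlapping genes are uncertain, as are those of near-identical copies such as the AKR1C, SAA, ALPP, ANXA8, keratin and histone families. The MCF7 table lists 58735 gene identifiers, 20734 of them with 0 counts. The MCF10A table lists 16155, none with fewer than 91 counts, so it had been filtered on low counts, a step that no note records. All identifiers were in GENCODE release 29, from which coordinates (GRCh38) were taken. Current symbols were found for 58207 identifiers of the MCF7 table and 16076 of the MCF10A table, all 15 columns matched the labels, and 0 columns were left out.

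Counts were analysed with edgeR 4.0.16 in R 4.3.3. Library totals of the whole table were scaled with TMM factors, and genes were kept by filterByExpr with its minimum count of 10. Groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. Unless another method is named, log2 fold changes, standard errors (SE) and adjusted p-values come from this test, and CPM values are counts per 1000000 of the TMM-scaled library total, given as mean ± SD. The MCF7 comparison used the 6 libraries of that line. The 3 MCF10A comparisons were contrasts of a single fit to all 9 libraries of that line, and the difference between the E545K effects of the 2 lines was an interaction contrast fitted to all 15 libraries on the genes in both tables. A fold change against a group with 0 counts is given as a lower bound, computed with a floor of 3 counts per library, and with 1 to 3 counts as a ratio with its exact 95% binomial interval. Such bounds and intervals cover counting error alone. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, part of which may be technical.

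A set of 44 gene lists (19 of metabolism, 13 of signalling, 5 of cell identity, 7 of technical quality and other cell types, 870 entries) was written before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. Of the entries, 1 had no identifier and 792 were in the MCF10A table. Lists with at least 5 tested members were tested with camera in limma 3.58.1, which asks whether a list's genes move relative to the other genes, at a preset inter-gene correlation of 0.01. All 44 lists were tested in MCF7 and 41 in the MCF10A comparisons. Members called are counted over all genes tested and, where that differs, adjusted over the list alone. Genes were named by rule: PIK3CA and PTEN throughout; the 8 highest and 8 lowest log2 fold changes per comparison with wild type (5 and 5 for the other comparisons) among called genes with at least 10 CPM in the higher group and replicates that did not overlap; up to 3 called members of each list with at least 5 CPM, and the largest called in the opposite direction; and 10 genes called alike in all 3 comparisons with wild type. Any other gene is said to have been chosen after its values were seen. Shared calls between comparisons were set beside the number expected of independent lists and, for the 2 comparisons that use the same wild-type libraries, beside 20 simulations with no group difference, since 3 control libraries cannot be split.

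The procedure was tested on simulated counts with the real means and library totals and 200 changed genes. In the MCF7 design (22213 genes), edgeR recovered 50.7% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 9 calls among the unchanged genes. In the MCF10A comparisons (16133 genes) it recovered 0% at each size with all 9 libraries, and 86.4%, 80.3% and 72.7% of 4-fold changes (E545K against WT, H1047R against WT and H1047R against E545K, 16147 genes) once the third library of each mutant group was left out. For the interaction it recovered 27.3% of 4-fold changes (16146 genes). The alternatives were DESeq2 size factors, no filter on low counts, a stricter filter (at least 1 CPM in all libraries of a group), DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, the 2 compared groups alone, the genes in both tables, a change of at least 2-fold, an estimated inter-gene correlation, and the rotation test fry. One alternative was added after the data were seen: the fit without the third library of each MCF10A mutant group, because these libraries resembled another group. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.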

Results

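RNA sequencing counts were available for 15 libraries of 2 human breast epithelial cell lines and their PIK3CA derivatives. MCF7 is an estrogen receptor-positive breast cancer line that carries E545K by origin, and MCF10A is a non-tumorigenic line with basal features. The 5 groups of 3 libraries each were MCF7 labelled WT, MCF7 labelled MUT (E545K in the series' design), and MCF10A labelled WT, E545K and H1047R. PIK3CA (ENSG00000121879, chromosome 3, 179148114 to 179240093, GRCh38) encodes the catalytic alpha subunit of phosphoinositide 3-kinase, with the codon of E545K in exon 10 and that of H1047R in exon 21 of 21. Counts per gene do not show which allele was transcribed, so they do not test the mutation labels. Library totals ranged from 128577455 to 162824466 counts in MCF7 and from 68740502 to 79922501 in MCF10A. The series addresses the prediction of cancer metabolism from gene expression, so genes of metabolic pathways were followed in each comparison.

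Marker genes placed 4 of the 9 MCF10A libraries apart from the other 5, and not by their labels. These markers were chosen after their values were seen. ERBB2, a receptor tyrosine kinase gene on 17q, was counted at 370 ± 18.2 CPM in the 3 libraries labelled WT and at 396 CPM in the third library labelled E545K. The first and second E545K libraries averaged 2.94 CPM, and the libraries labelled H1047R 3.50 ± 0.730 CPM (n = 3). The luminal keratin KRT19 read 6471 to 8791 CPM in the WT-labelled libraries, 6448 CPM in the third E545K library and at most 5.38 CPM in the other 5. The basal keratin KRT5 read 0.422 to 0.692 CPM in the WT-labelled libraries, 0.574 CPM in the third E545K library and at least 1904 CPM in the other 5. CDKN2A, a cell-cycle inhibitor gene that MCF10A cells lack, read 4.16 to 5.57 CPM in the WT-labelled libraries and 4.99 CPM in the third E545K library, against 0 counts in the other 5. Across genes, the third E545K library had Spearman coefficients of 0.982 to 0.995 with the WT-labelled libraries and of 0.748 to 0.753 with the other E545K libraries. The third H1047R library reached 0.988 to 0.99 with the first 2 E545K libraries and 0.978 to 0.981 with the other H1047R libraries. Mitochondrial transcripts took 16.8% and 16.4% of counts in the second WT-labelled library and the third E545K library, 8.16% and 8.46% in the other WT-labelled libraries, and at most 4.47% in the other 5. Every MCF10A comparison with wild type therefore sets libraries with basal transcripts against libraries with luminal transcripts, with 1 luminal library on the E545K side.

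**Figure D1:**
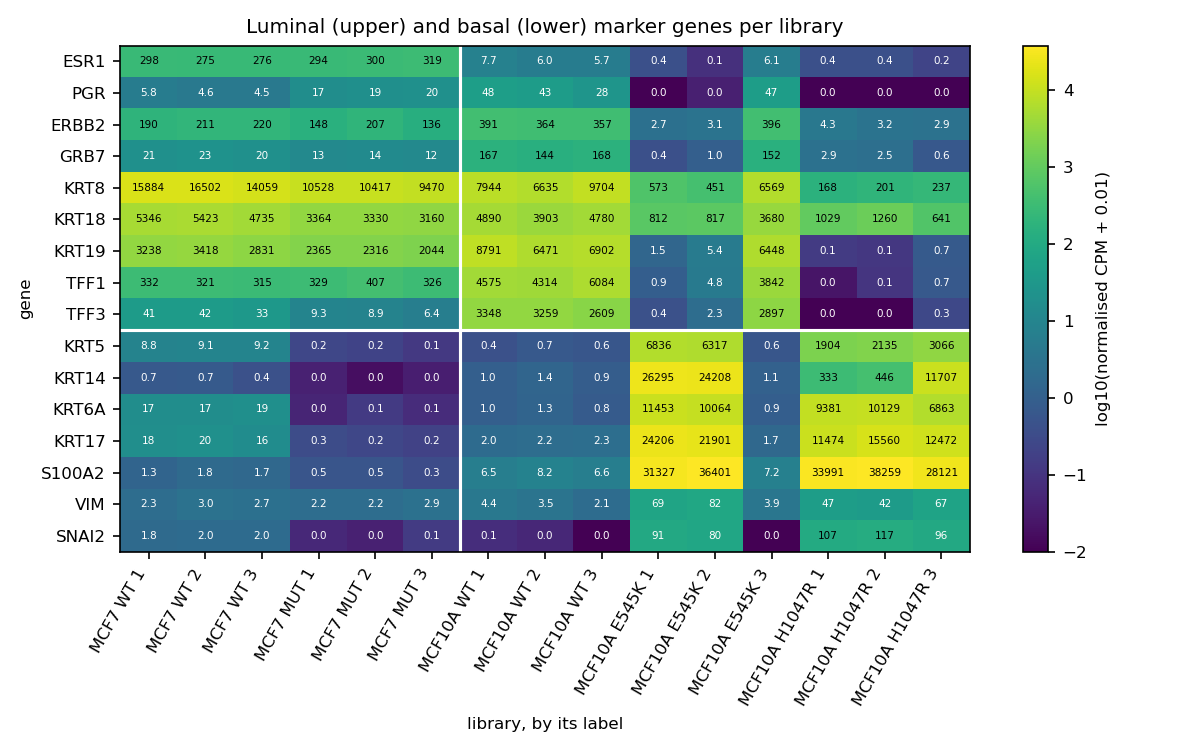
Normalised CPM (printed, and as log10(CPM + 0.01) in colour) of 16 luminal and basal marker genes in each of the 15 libraries. The third MCF10A library labelled E545K shows the luminal pattern of the libraries labelled WT (KRT19 at 6448 CPM), and the other 5 mutation-labelled libraries the basal pattern.

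**Figure D2:**
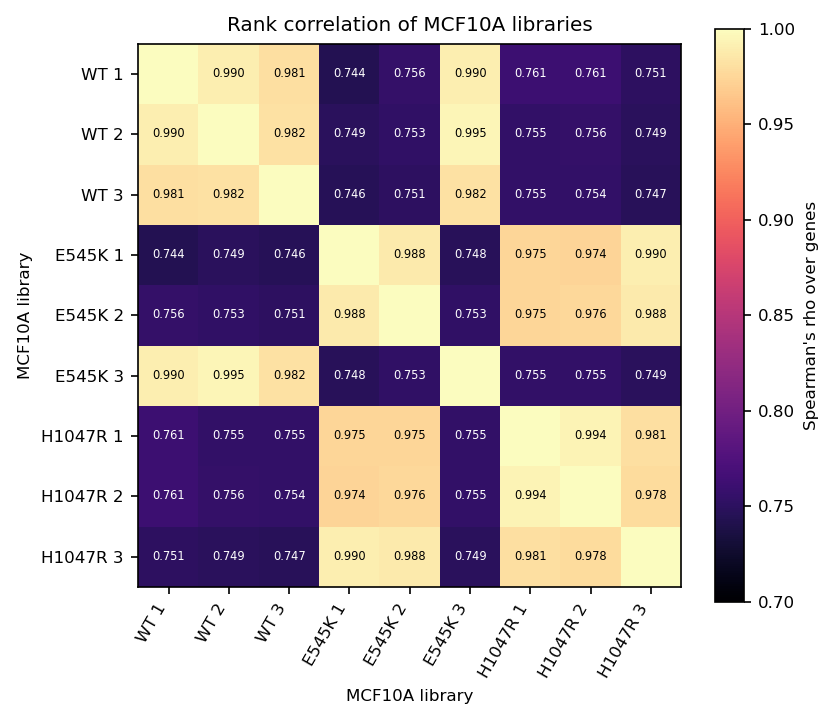
Spearman coefficients over genes for each pair of the 9 MCF10A libraries (colour and printed value). The third E545K library correlates at 0.982 or more with the WT-labelled libraries and at 0.753 or less with the other E545K libraries.

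The MCF7 comparison asked which genes differ between cells labelled MUT and WT. PIK3CA was counted at 30.1 ± 4.95 CPM in MUT and 18.4 ± 1.02 CPM in WT libraries (n = 3 each), a log2 fold change of 0.71 (SE 0.12, adjusted p = 3.51e-05). It lies on a part of chromosome 3 where most genes were higher in MUT: the median log2 fold change was 0.80 over 15 genes from 175 to 180 Mb. PTEN, which opposes PI3K, did not differ beyond the spread between libraries (117 ± 16.4 and 120 ± 3.10 CPM, log2 fold change -0.04, adjusted p = 0.827). In all, 8746 of 22213 tested genes were called, 4231 higher and 4515 lower in MUT, 3249 of them changed at least 2-fold. The labels do not say how either group of MCF7 cells was derived. Effects of E545K on genes or lists therefore cannot be told apart from other differences between these groups of cells. The largest chromosome-wide median log2 fold changes were 0.5 on chromosome 18, 0.36 on chromosome 9 and -0.36 on chromosome 14.

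The largest increases in MUT were all on chromosome 18. ME2, the mitochondrial malic enzyme that turns malate into pyruvate, read 29.7 ± 5.00 CPM in MUT and had 0 counts in WT libraries, at least 1440-fold higher. SMAD4, which carries TGF-beta signals to the nucleus, read 25.3 ± 2.01 CPM against 0 counts, at least 1230-fold higher. MOCOS, C18orf63, POLI, RAB27B and C18orf54 also had 0 counts in WT libraries and were at least 995-, 919-, 725-, 704- and 636-fold higher. MBD2, a reader of methylated DNA, read 58.7 ± 6.77 CPM against 0.0125 ± 0.0217 CPM (log2 fold change 11.99, SE 0.28). From ME2 to RAB27B (50878734 to 54895516), 8 of the 9 genes expressed in MUT lay under 1% of their MUT level in WT.

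**Figure D3:**
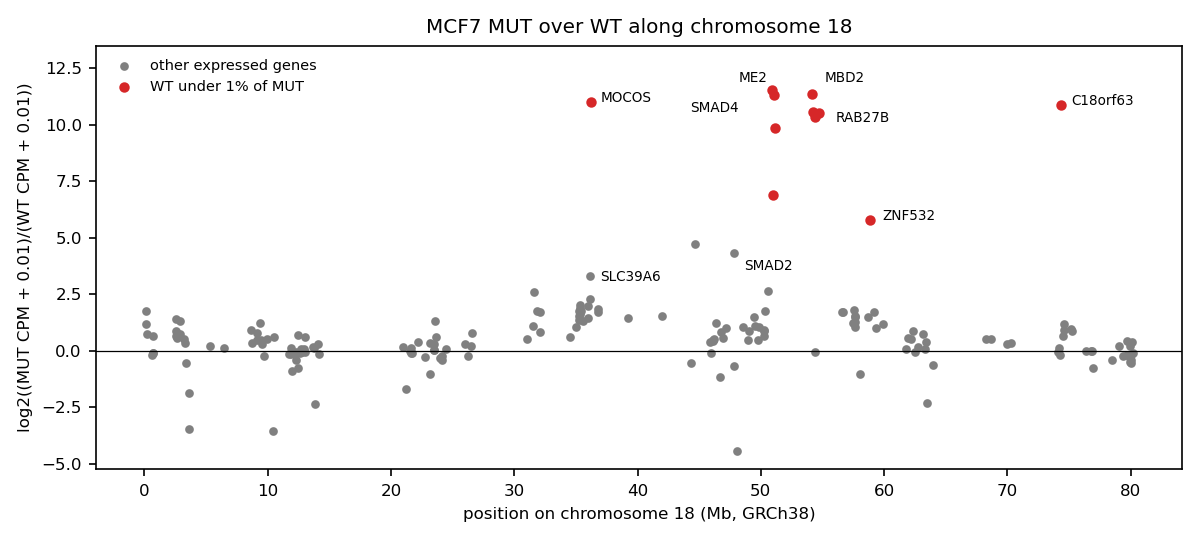
Log2 ratio of mean CPM in MCF7 MUT over WT (0.01 added to both) for expressed genes along chromosome 18, in Mb. The 11 genes under 1% of the MUT level in WT (red) include ME2, SMAD4, MBD2 and RAB27B.

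The 8 largest decreases in MUT included keratinocyte genes. The placental phosphatase ALPP, which has a near-identical neighbour, fell from 77.1 ± 8.45 CPM in WT to 0.0169 ± 0.0117 CPM in MUT (log2 fold change -12.09, SE 0.22). KRT4, a keratin of moist stratified epithelium, fell from 113 ± 2.40 to 0.183 ± 0.0243 CPM (-9.27, SE 0.15, adjusted p = 4.2e-21). PCSK9, which lowers LDL receptor levels, fell from 13.0 ± 0.557 CPM in WT by a log2 fold change of -10.28 (SE 0.31). PSAPL1, TNR, KLHDC7B, CASP14 and KLK5 changed by -10.81, -10.07, -8.27, -8.22 and -8.20 on the log2 scale.

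Among the lists, 7 moved down and 2 up in MUT. Squamous differentiation genes were called lower in 19 of 19 members (median log2 fold change -3.91, camera adjusted p = 1.55e-69, and 0.0231 with an estimated correlation), among them SBSN (28.8 ± 1.68 to 0.165 ± 0.0127 CPM) and S100A7 (24.0 ± 1.90 to 0.164 ± 0.0724 CPM). It was the only list called with an estimated correlation. The type I interferon response, the antiviral gene program, was lower in 25 of 26 members and higher in 0 (adjusted over the list alone, 25 lower and 1 higher; median -3.03, adjusted p = 1.13e-61, and 0.106 with an estimated correlation). OAS2 fell from 43.8 ± 10.8 to 0.399 ± 0.0205 CPM, IFI27 from 48.2 ± 6.22 to 1.27 ± 0.137 CPM and IFIT1 from 59.0 ± 14.8 to 1.73 ± 0.199 CPM. Basal and myoepithelial markers were lower in 12 of 18 and higher in 2 (median -1.67, adjusted p = 9.55e-12, and 0.115 with an estimated correlation). KRT6A, KRT17 and KRT5 changed by -7.91, -6.15 and -5.62, while DST rose 2-fold from 84.2 ± 7.86 to 170 ± 24.3 CPM. NF-kB and cytokine genes were lower in 14 of 18 (median -1.89, adjusted p = 2.78e-07, and 0.393 with an estimated correlation), including LIF (-2.17), RELB (-1.86) and the NF-kB inhibitor NFKBIA (114 ± 9.49 to 63.3 ± 0.595 CPM). Genes that FOXO factors induce when AKT is inactive were lower in 14 of 21 and higher in 3 (15 lower adjusted over the list alone; median -0.64, adjusted p = 3.36e-06, and 0.106 with an estimated correlation). PDK4, which restrains pyruvate oxidation, changed by -4.36 (SE 0.18), the ubiquitin ligase FBXO32 by -3.84 (SE 0.13) and EPAS1 by -2.72 (SE 0.13), while IRS2, an insulin receptor substrate, rose from 9.25 ± 0.0241 to 53.2 ± 2.27 CPM.

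The other 4 called lists were 2 that moved down and 2 that moved up. NRF2 targets were lower in 9 of 20 and higher in 4 (median -0.16, adjusted p = 5.72e-03, and 0.34 with an estimated correlation), with ABCC3 at -2.82 and AKR1C2 at -2.52 but the cystine importer SLC7A11 at 1.96. Mesenchymal genes were lower in 9 of 16 and higher in 2 (10 lower adjusted over the list alone; median -0.78, adjusted p = 3.49e-03, and 0.591 with an estimated correlation), among them the collagens COL6A2 (-0.94) and COL5A1 (-0.93). Mitotic genes were higher in 18 of 22 and lower in 0 (median 0.33, adjusted p = 4.11e-03, and 0.776 with an estimated correlation): the spindle kinase AURKA rose from 126 ± 8.65 to 258 ± 26.3 CPM, with UBE2C at 0.77 and CENPE at 0.67. Replication-dependent histones were higher in 13 of 16 and lower in 0 (14 higher adjusted over the list alone; median 1.37, adjusted p = 4.03e-12, and 0.34 with an estimated correlation), H2BC21 by 1.91 and H2BC5 from 12.6 ± 1.04 to 43.1 ± 2.14 CPM.

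None of the 19 metabolism lists passed the threshold in MCF7, and their medians lay between -0.18 and 0.21, but single enzymes changed. PHGDH, which opens serine synthesis, rose from 33.0 ± 3.95 to 163 ± 10.4 CPM (2.30, SE 0.11), while GLDC, which breaks down glycine, fell from 10.7 ± 0.711 to 2.07 ± 0.0647 CPM (-2.36, SE 0.13). Glutamine synthetase (GLUL) fell from 368 ± 5.77 to 88.3 ± 2.91 CPM (-2.06, SE 0.10), and the neuronal-type glucose carrier SLC2A3 from 11.2 ± 0.422 to 1.07 ± 0.185 CPM (-3.39, SE 0.15). GGT1, which recycles glutathione, rose from 2.43 ± 0.422 to 12.2 ± 2.68 CPM. The subunits of the large neutral amino acid carrier, SLC7A5 and SLC3A2, fell from 11200 to 6320 CPM and from 2333 to 1455 CPM. Glycolysis genes were higher in 3 and lower in 6 of 23 (median -0.11, adjusted p = 0.57). Cholesterol genes were higher in 11 and lower in 1 of 25, IDI1 by 0.57 and MSMO1 by 0.52, with a median of 0.21 but a mean of -0.19 because of PCSK9. Median, mean and test also differed in sign in 16 other lists, none of them past the threshold. Of the signalling lists not called, estrogen receptor targets came nearest (9 higher and 4 lower of 22, adjusted p = 0.0744): SLC39A6 on chromosome 18 rose from 130 ± 12.8 to 1270 ± 153 CPM, CXCL12 from 18.8 ± 0.0641 to 139 ± 13.7 CPM, and TFF3 fell from 38.7 ± 5.06 to 8.21 ± 1.57 CPM. MYC itself fell from 341 ± 19.8 to 150 ± 3.10 CPM, with 1 of 22 genes of the MYC list higher and 7 lower. In the PI3K pathway list PIK3CD changed by -1.63 and INPP4B by 0.80.

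**Figure D4:**
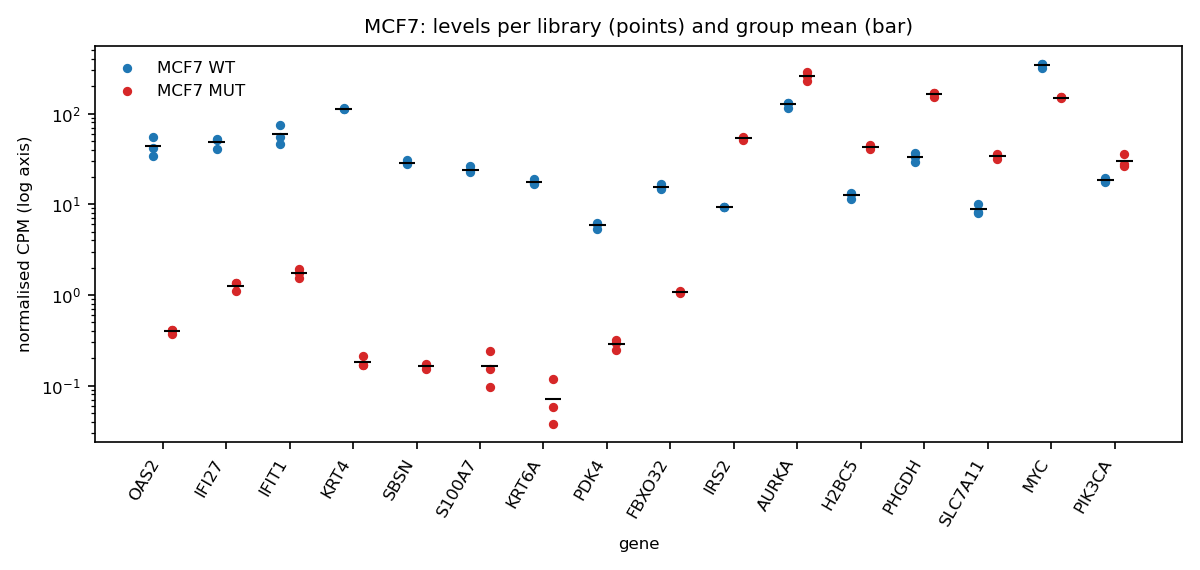
Normalised CPM (log axis) of 16 genes in the 3 MCF7 WT and 3 MUT libraries (points) with the group mean (bar). Interferon, squamous and FOXO-induced genes such as OAS2, KRT4 and FBXO32 sit lower in MUT, while IRS2, PHGDH and SLC7A11 sit higher.

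The H1047R comparison asked what separates MCF10A libraries labelled H1047R from those labelled WT. PIK3CA read 3.96 ± 0.955 CPM in H1047R and 3.10 ± 0.0949 CPM in WT-labelled libraries (log2 fold change 0.36, SE 0.24, adjusted p = 0.244, n = 3 each), and PTEN 14.3 ± 0.884 and 16.3 ± 1.29 CPM (-0.19, adjusted p = 0.326). SERPINE1, an inhibitor of plasminogen activation, read 417 ± 301 CPM against 3 counts in all WT-labelled libraries together, a ratio between 10400 and 148000. SDHAF3, ZBED2, FST, ALKBH3, PRSS21 and MYOSLID had 0 counts in WT-labelled libraries and were at least 1040-, 969-, 923-, 731-, 725- and 713-fold higher, and ANXA8L1 read 470 ± 163 against 0.0181 ± 0.0158 CPM. In the other direction, the luminal transcription factor SPDEF (153 ± 22.7 CPM in WT) and the gluconeogenic enzyme FBP1 (127 ± 12.4 CPM) had 0 counts in H1047R, at least 3690- and 3060-fold lower. FAM3B, QPRT and ANKRD30A were at least 1470-, 1460- and 1080-fold lower. BCAS1 and IGFBP5 kept 1 and 3 counts, for ratios of WT to H1047R between 11900 and 2610000 and between 12900 and 182000. TFF3 fell from 3072 ± 403 to 0.0884 ± 0.153 CPM.

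Of 16133 tested genes, 7074 were called, 3657 higher and 3417 lower in H1047R, 6032 of them changed at least 2-fold, with no adjusted p below 0.0305. The replicate block left 2310 calls, 1260 higher and 1050 lower. Lower calls outnumbered higher ones in limma-voom (2666 higher, 3680 lower), without the first (3621 and 3860), second (3551 and 3859) or the third E545K library (5154 and 5465), without the third library of both mutant groups (5047 and 5450) and with only the 2 compared groups fitted (4997 and 5409). With the third E545K library in the fit, the count was 0 without any single WT-labelled or H1047R library (lowest adjusted p 0.0718 to 0.0875). It did not rest on the third H1047R library, since it was 10497 without the third library of both mutant groups. It was 7481, 7410 and 10619 without the first, the second and the third E545K library. These libraries take part only through the shared estimate of the spread, the gene filter and the scaling. The common biological coefficient of variation was 56.4% over the 9 MCF10A libraries, 20.9% without the third library of each mutant group, and 12.2% in MCF7.

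Camera called 16 lists, 10 up and 6 down, and 0 of them with an estimated correlation (adjusted p = 0.68 to 0.695). Basal markers were higher in 18 of 19 (median 10.10, camera adjusted p = 1.13e-09), with KRT6A at 8791 ± 1710 against 1.03 ± 0.288 CPM, KRT17 at 13170 ± 2130 against 2.19 ± 0.166 CPM and S100A2 at 33460 ± 5090 against 7.10 ± 0.917 CPM. Mesenchymal genes were higher in 14 of 18 (median 4.32, adjusted p = 2.34e-06), among them SNAI2 (107 ± 10.4 against 0.0357 ± 0.0326 CPM) and TGFBI (1132 ± 15.7 against 2.39 ± 0.526 CPM). Luminal markers were lower in 14 of 15 (15 adjusted over the list alone; median -6.04, adjusted p = 2.23e-06), KRT19 from 7388 ± 1230 to 0.326 ± 0.361 CPM. Estrogen receptor targets were lower in 15 of 22 (17 lower and 1 higher adjusted over the list alone; median -4.35, or -4.25 with 2 members at their bound, adjusted p = 8.30e-05): TFF1 fell from 4991 ± 955 to 0.260 ± 0.362 CPM, and PGR from 39.6 ± 10.5 CPM to 0 counts, at least 955-fold lower. Mitotic genes were higher in 18 of 22 and lower in 1 (median 1.64, adjusted p = 2.50e-06), with MKI67 at 3.06, CCNB1 at 2.53 and CDC20 at 2.39 but AURKA at -1.43. MYC targets were higher in 17 of 22 and lower in 1 (20 higher adjusted over the list alone; median 1.28, adjusted p = 4.22e-05): MYC rose from 16.9 ± 3.01 to 157 ± 4.94 CPM, LDHA from 1198 ± 289 to 8969 ± 1130 CPM and NPM1 by 2.45, against TFRC at -2.34. NF-kB and cytokine genes were higher in 14 of 19 and lower in 1 (16 higher adjusted over the list alone; median 6.49, or 4.03 with the 3 members at 0 counts in a group placed at their bound, adjusted p = 5.61e-05), CSF3 by 12.07 and SAA1 to 547 ± 363 CPM, with NFKBIA at -0.64. MAPK output genes were higher in 11 of 16 and lower in 1 (12 and 3 adjusted over the list alone; median 1.94, adjusted p = 1.13e-03), FOSL1 from 0.118 ± 0.0523 to 101 ± 19.5 CPM and PHLDA1 by 6.12.

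In this comparison 3 metabolism lists passed the threshold, 0 of them with an estimated correlation. Glycolysis genes were higher in 11 of 23 and lower in 2 (median 0.87, adjusted p = 6.40e-03). The lactate carriers SLC16A1 and SLC16A3 rose from 0.517 ± 0.204 to 75.8 ± 13.1 CPM and from 0.252 ± 0.192 to 11.7 ± 0.809 CPM, ALDOC rose by 6.33 and hexokinase HK1 fell by 0.79 on the log2 scale. Branched-chain amino acid catabolism was lower in 9 of 15 (11 adjusted over the list alone; median -1.08, adjusted p = 6.20e-04), with PCCB at -2.61, PCCA at -2.28 and MCCC1 at -2.07. The mitochondrially encoded respiratory chain had 0 of 13 members called but a median of -1.32 (adjusted p = 3.37e-02). FOXO-induced genes were lower in 10 of 20 and higher in 2 (11 lower adjusted over the list alone; median -1.34, adjusted p = 4.62e-02), PIK3IP1 at -6.71 and FBXO32 at -3.44, against EPAS1 at 2.53. The remaining calls were p53 targets (11 higher and 2 lower of 22, 12 higher adjusted over the list alone, median 1.67, adjusted p = 6.40e-03, FAS at 9.72 and TP53I3 at 5.71), squamous differentiation (9 higher and 3 lower of 20, median 1.92, adjusted p = 4.28e-02), ribosomal proteins (17 higher and 1 lower of 34, 21 higher adjusted over the list alone, median 0.98, adjusted p = 4.33e-05) and histones (9 lower of 16, 12 adjusted over the list alone, median -2.02, adjusted p = 1.65e-04). Among ribosomal proteins RPS23 rose by 3.20 and RPS6 by 2.87, while RPL19, which lies beside ERBB2 on 17q, fell from 28270 ± 1830 to 1971 ± 195 CPM. The other 25 tested lists were not called, and median, mean and test differed in sign in 7 of them.

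**Figure D5:**
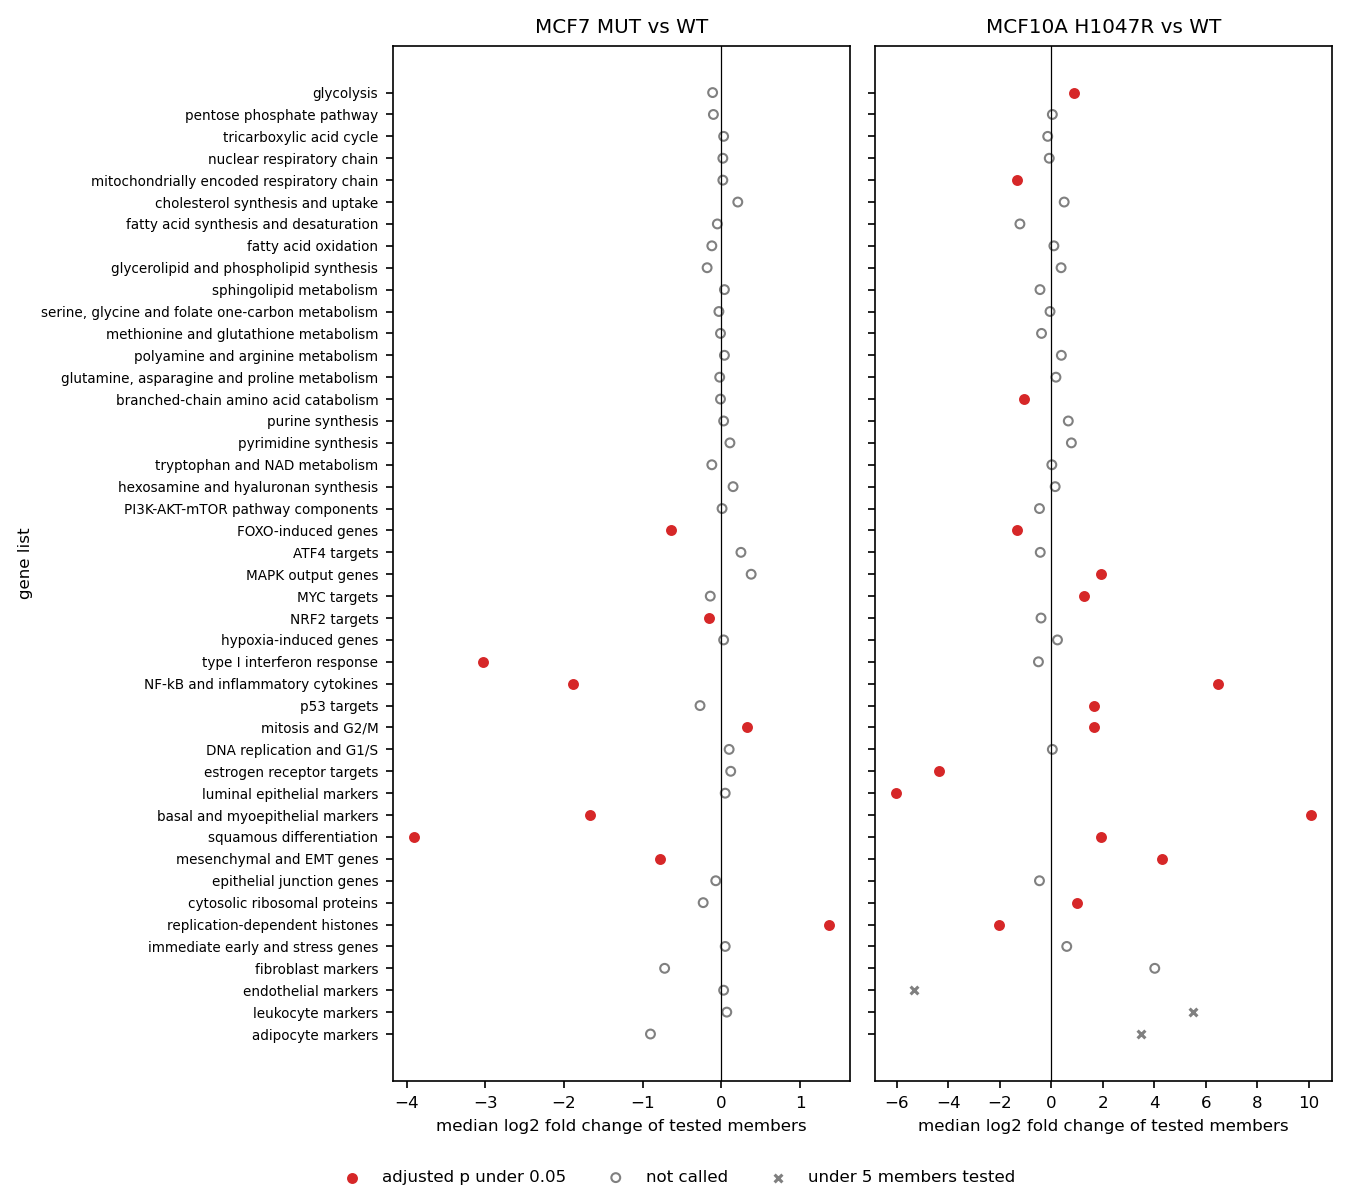
Median log2 fold change of the tested members of each of the 44 gene lists in MCF7 MUT against WT (left) and MCF10A H1047R against WT (right), with lists past the camera threshold in red. Squamous differentiation has the lowest median in MCF7 (-3.91), and basal markers have the highest in MCF10A (10.10).

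The E545K comparison in MCF10A had the third E545K library among its 3, which shows the luminal pattern. PIK3CA read 2.80 ± 0.299 CPM in E545K and 3.10 ± 0.0949 CPM in WT-labelled libraries (log2 fold change -0.14, SE 0.24, adjusted p = 0.675), and PTEN 16.2 ± 1.54 and 16.3 ± 1.29 CPM (-0.01, adjusted p = 0.978). With all libraries edgeR called 0 of 16133 genes (lowest adjusted p 0.11), 4384 had an unadjusted p under 0.05, DESeq2 called 2446 (2270 higher, 176 lower) and limma-voom 0. Without the third E545K library alone edgeR called 10273 genes, and without the third library of both mutant groups 10717, 5347 higher and 5370 lower of 16147. In that last fit the basal keratin KRT14 read 25250 ± 1480 CPM in the first 2 E545K libraries and 1.06 ± 0.257 CPM in the WT-labelled ones (14.54, SE 0.34). SDHAF3, ZBED2, QRFPR and ALKBH3 had 0 counts in WT-labelled libraries and were at least 1120-, 694-, 648- and 641-fold higher. HSPB8, HGD and SLC40A1 had 0 counts in the first 2 E545K libraries and were at least 851-, 763- and 668-fold lower. With all libraries, camera placed 9 lists up and 5 down, 0 of them called with an estimated correlation (adjusted p = 0.609 to 0.665). The lists that moved up were glycolysis (median 0.60), MAPK output (1.62), MYC targets (1.19), NF-kB and cytokines (6.14, or 3.88 with 3 members at their bound), p53 targets (1.66), mitosis (1.04), basal markers (8.94), mesenchymal genes (3.90) and ribosomal proteins (0.82). Those that moved down were branched-chain catabolism (-0.62), estrogen receptor targets (-1.29), luminal markers (-1.57), epithelial junctions (-0.57) and histones (-1.01). No member of these lists was called over all genes. Adjusted over the list alone, members were higher in glycolysis (10 of 23), MAPK output (10 of 16), MYC targets (15 of 22), NF-kB and cytokines (14 of 19), p53 targets (15 of 22), mitosis (12 of 22), basal markers (18 of 19), mesenchymal genes (13 of 18) and ribosomal proteins (9 of 34), and 0 were called in the 5 lists that moved down. Median, mean and test differed in sign in 7 lists not called.

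The direct comparison of the MCF10A mutants asked whether H1047R and E545K differ. PIK3CA read 3.96 ± 0.955 CPM in H1047R and 2.80 ± 0.299 CPM in E545K libraries (0.50, SE 0.24, adjusted p = 0.392), and PTEN differed by -0.18 (adjusted p = 0.61). edgeR called 0 of 16133 genes (lowest adjusted p 0.376), 2127 had an unadjusted p under 0.05, DESeq2 called 247 (45 higher, 202 lower) and limma-voom 0. Without the third E545K library alone 0 genes were called (lowest adjusted p 0.09). Without the third library of both groups 978 genes were called, 485 higher and 493 lower in H1047R. The third H1047R library was left out of that fit for its likeness to the first 2 E545K libraries. This choice itself favours a difference between the groups, so the calls of that fit do not test one. The tight-junction gene CLDN4 then read 66.6 ± 3.96 against 0.785 ± 0.349 CPM (6.40, SE 0.35, n = 2 each), the protease gene MMP10 22.0 ± 1.92 against 0.704 ± 0.213 CPM, TSPAN1 214 ± 1.48 against 22.7 ± 0.414 CPM and PRSS3 127 ± 11.9 against 14.4 ± 0.0591 CPM, with SPRR1A at 4.03. KRT14 read 389 ± 79.9 against 25250 ± 1480 CPM (-6.02, SE 0.30), and in the third H1047R library 11707 CPM. SAA2, PLCB1, the EGF-receptor ligand AREG and H2AC6 were lower in H1047R by -4.52, -3.00, -2.44 and -2.39 on the log2 scale. In this fit 6 lists passed, 0 of them with an estimated correlation: epithelial junctions (8 higher and 0 lower of 24, adjusted p = 4.41e-09, and 0.173 with an estimated correlation) and mitosis (adjusted p = 5.74e-03) up, and NF-kB and cytokines (adjusted p = 1.69e-06), p53 targets (adjusted p = 7.54e-05), ATF4 targets (adjusted p = 1.72e-02) and histones (adjusted p = 5.74e-03) down. Members lower were 4 of 19, 5 of 22, 4 of 18 and 3 of 16 in the last 4 lists, and 7, 9, 6 and 6 adjusted over the list alone, where 9 junction genes were higher. With all libraries camera called 14 lists, luminal markers (median -4.47) and estrogen receptor targets (-2.77) with the largest shifts, 0 of them with an estimated correlation (adjusted p = 0.75). The others were cholesterol synthesis (0.19), MAPK output (0.46), MYC targets (0.19), NF-kB and cytokines (0.16), mitosis (0.52), basal markers (0.50), squamous differentiation (0.31), mesenchymal genes (0.40) and ribosomal proteins (0.20) up, and the mitochondrially encoded respiratory chain (-0.89), branched-chain catabolism (-0.82) and histones (-0.81) down. No member was called over all genes, and adjusted over the list alone only 9 of 15 luminal markers and 6 of 22 estrogen receptor targets were, all lower. Median, mean and test differed in sign in 15 lists not called.

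The interaction asked whether E545K goes with different changes in MCF7 and MCF10A, again with the luminal library on the E545K side. The PIK3CA change was larger in MCF7 by 0.86 on the log2 scale (SE 0.29, adjusted p = 0.0679), and that of PTEN differed by -0.03 (adjusted p = 0.936). In all, 2034 of 16146 genes differed, 476 with the higher change in MCF7 and 1558 with the higher change in MCF10A. The count fell to 336 with the replicate block and to 786 to 1088 without one MCF7 library. The balance turned in limma-voom (1665 and 733), without the third E545K library (5414 and 4524) and without the third library of both mutant groups (5648 and 4747). The chromosome 18 genes SMAD4, POLI, RAB27B, ME2 and C18orf54 stood highest, since they had 0 counts in MCF7 WT and were counted in both MCF10A groups (SMAD4 at 8.31 and 9.96 CPM, ME2 at 25.3 and 11.3 CPM in E545K and WT-labelled libraries). ANXA8L1, KRT6A, CHRNA9, CAVIN2 and GNA15 stood lowest: KRT6A fell from 17.6 to 0.0724 CPM in MCF7 and averaged 7172 CPM in MCF10A E545K against 1.03 CPM in WT-labelled libraries. Camera called 13 lists, 2 of them with an estimated correlation. It placed 4 higher in MCF7, histones (median 2.57), luminal markers (1.56), estrogen receptor targets (1.33) and branched-chain catabolism (0.47). The 9 lists with the lower change in MCF7 were type I interferon (-2.67, 12 of 23 members called, adjusted p = 4.62e-12, and 0.0163 with an estimated correlation), squamous differentiation (-5.22, 15 of 20, adjusted p = 4.62e-12, and 0.0448), basal markers (-10.51), NF-kB and cytokines (-6.86), mesenchymal genes (-4.68), p53 targets (-1.70), MYC targets (-1.33), ribosomal proteins (-0.99) and glycolysis (-0.57). Adjusted over the list alone, members lower numbered 15 of 23 for interferon, 16 of 20 for squamous, 17 of 19 for basal, 18 of 19 for NF-kB, 15 of 19 for mesenchymal, 18 of 22 for MYC, 21 of 34 for ribosomal and 8 of 23 for glycolysis genes, while 12 of 16 histones and 0 luminal markers (1 over all genes) were higher. The other 11 were not called with an estimated correlation (adjusted p = 0.392 to 0.622), and median, mean and test differed in sign in 5 lists not called.

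Shared calls asked which changes recur across comparisons. With all libraries 0 genes were called alike for E545K and H1047R in MCF10A and 0 alike for E545K in MCF7 and MCF10A, since the MCF10A E545K comparison had no calls in edgeR. DESeq2 shared 2308 genes between the MCF10A mutants, 2163 higher and 145 lower against 650.2 and 43.52 for independent lists, with 0 in opposite directions against 611.8. The mutants share their WT-labelled libraries, so independence is not the value without a change, and DESeq2 was not simulated. Between the lines it shared 464, 439 higher and 25 lower against 473.2 and 33.68 for independent lists, with 656 in opposite directions against 435.6. Log2 fold changes of the 2 MCF10A mutants had a covariance of 5.56 across genes, against 0.382 in simulations where only the WT-labelled libraries were shared. These simulations had no group difference, so shared calls near 0 were fixed in advance. WT-labelled libraries of other cells would give both mutants the same changes, and this was not simulated. The shared calls are therefore no sign of an effect common to the 2 mutations. Without the third library of each mutant group, 9078 genes were called alike in both mutants (4446 higher, 4632 lower) and 30 in opposite directions, against 1671 higher and 1813 lower for independent lists and 0 in the simulations, at a covariance of 10.17 against 0.0563. Between the lines that fit shared 2351 genes in one direction (1189 higher, 1162 lower) and 2340 in opposite directions, against 1162 higher, 1018 lower and 2186 opposite for independent lists. MCF7 MUT and MCF10A H1047R shared 1571 in one direction (823 higher, 748 lower) and 1643 in opposite directions with all libraries, against 780.8, 646.5 and 1425 for independent lists. This overlap was 0 in either direction without any one MCF10A library labelled WT or H1047R, with the third E545K library kept in the fit. Without the third library of both mutant groups it was 2278 in one direction (1128 higher, 1150 lower) and 2313 in opposite directions. Independent lists would give 1093, 1034 and 2146.

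Without the third library of each mutant group, 992 genes were higher and 1020 lower in all 3 comparisons with wild type, against 956 and 874.9 if the MCF7 calls were independent of the 4035 and 4359 genes called alike in both MCF10A mutants. The 10 named by the rule were all lower: FBXO32, the atrophy-linked ubiquitin ligase that FOXO induces (-3.84 in MCF7, -3.95 for E545K and -3.34 for H1047R in MCF10A), EFHD1 (-4.26, -10.38 and -12.18), NRCAM (-2.94, -4.09 and -3.80), S100A4 (-2.36, -3.09 and -2.77), and B4GALNT2, CALML5, PADI2, TFF3, TMEM150C and S100P.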

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

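The tests of the chromosome 18 pattern were chosen after the result was seen, and the splits of the libraries were planned before. What drew attention here is a tested difference between the cell lines: 2034 genes and 13 gene lists had E545K changes that differed between MCF7 and MCF10A in the interaction contrast. The 10 genes named by the rule had fitted log2 differences of 14.11 (SMAD4), 13.87 (POLI), 13.78 (RAB27B), 12.94 (ME2), 12.01 (C18orf54), -25.29 (ANXA8L1), -20.62 (KRT6A), -20.24 (CHRNA9), -19.35 (CAVIN2) and -19.27 (GNA15). Where a group had 0 counts the fitted value depends on the prior count and is no bound. Of the 50 splits of the libraries, 1 called as many genes, the real one, and the highest other split called 537. The splits regrouped the MCF7 and MCF10A libraries together, so a difference between the MCF7 groups alone could make the real count the highest. They therefore do not decide whether the E545K changes differ between the lines. For the 13 lists chance is not excluded, since 23 of the 50 splits called as many and the highest other called 18. Because 1 of the 3 E545K libraries and all 3 WT-labelled libraries of MCF10A carry luminal transcripts, the interaction does not isolate an effect of E545K.

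The first pattern is the group of chromosome 18 genes near 0 in the MCF7 libraries labelled WT. Genes under 1% of their MUT level in WT made up 11 of 184 expressed genes on chromosome 18 (5.98%) and 13 of 13669 elsewhere (0.0951%), a ratio of shares of 62.9 (two-sided Fisher exact p = 3.61e-15). This p-value takes genes as independent, but 8 of the 11 lay from ME2 to RAB27B, so it overstates the evidence if they went off together. MOCOS, ZNF532 and C18orf63 lay singly elsewhere, beside neighbours expressed in WT (TPGS2 at 29.3, SEC11C at 10.4 and CNDP2 at 80.6 CPM). A loss of parts of chromosome 18 in the WT-labelled line may account for these 11 genes, but loss of a single stretch would not cover them all. The hypothesis was found and tested on the same counts, and DNA copy number was not measured. An effect of E545K of the same size in both lines would raise the same genes by a log2 difference of at least 6.6 in MCF10A, where their median was 1.11 over 10 genes (interquartile range 1.85, the third mutant libraries left out). This stays open despite the low value, because the MCF10A libraries labelled WT may hold another line and so do not measure an E545K effect.

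The 6 MCF7 libraries make 10 splits, too few for a share under 0.05: the real split called 8746 genes and the highest other 0. For lists the real split called 9, 5 of the 10 splits called as many, and the highest other called 15. The same limit holds for each MCF10A comparison. For H1047R against WT the real split called 7074 genes, the highest other 0, and 16 lists, with 2 of 10 splits as high and the highest other at 18. For E545K against WT the real count was 0, which all 10 of 10 splits reached, and the highest other called 7. Its lists numbered 14, with 4 of 10 splits as high and the highest other at 16. For H1047R against E545K the real count was 0, which 10 of 10 splits reached, and the highest other called 23. Its lists numbered 14, with 7 of 10 splits as high and the highest other at 16. For the shared calls of the MCF10A mutants, with 0 in the real split, 60 of 60 splits gave as many and the highest other gave 5. For those of E545K in both lines, also 0 in the real split, 100 of 100 splits gave as many and the highest other gave 0. Every split reaches a real count of 0, so the splits say nothing about the counts of 0 given here.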

How the results depend on the processing

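The fit without the third library of each MCF10A mutant group was chosen after the data were seen, and all other alternatives were planned. In MCF7 the 8746 called genes ranged from 6731 (genes in both tables) to 9972 (without the second MUT library) over the alternatives other than a change of at least 2-fold, and from 7143 (without the second WT library) with a library left out. No named gene that was called with all libraries turned direction under any alternative. E545K against WT in MCF10A and H1047R against E545K had no such gene, so this was not tested for them. The only called lists whose test turned direction were in H1047R against E545K. Where a count moved by over 1.5 times the values follow, and the cause was not tested unless the alternative has fewer libraries.

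With DESeq2, E545K against WT called 2446 genes instead of 0, H1047R against E545K 247 instead of 0, the interaction 3656 instead of 2034, the MCF10A mutants shared 2308 and the lines 464. With the replicate block, H1047R against WT called 2310 instead of 7074 and the interaction 336 instead of 2034, and MCF7 MUT and MCF10A H1047R shared 507 instead of 1571 (277 higher against 278.2 for independent lists) with 633 opposite, although replicate numbers did not pair the samples. In MCF7, deviations from the group means correlated at -0.449 to 0.422 between MUT and WT libraries with other numbers, and at -0.055 to 0.088 with the same number. A pairing under other numbers was not tested. A change of at least 2-fold left 3249 genes in MCF7, and 404 alike and 563 opposite in the overlap of MCF7 MUT with MCF10A H1047R. Without the third mutant libraries, the counts were 10717 for E545K against WT, 978 for H1047R against E545K (6 lists), 10395 for the interaction, 9078 shared by the mutants and 2351 shared by the lines. With an estimated inter-gene correlation the called lists fell to 1 in MCF7, 0 for E545K, 0 for H1047R, 0 between the mutants and 2 in the interaction. The rotation test fry called 22 lists in MCF7, 0 for E545K and 0 between the mutants.

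With each library left out in turn, H1047R against WT ranged from 0 (without any one WT-labelled or H1047R library) to 10619 (without the third E545K library). E545K against WT ranged from 0 to 10273, the mutants' shared calls from 0 to 9225 and the lines' from 0 to 2233, each highest without the third E545K library. H1047R against E545K called 0 in each case. The overlap of MCF7 MUT with MCF10A H1047R ranged from 0 (without any one MCF10A library labelled WT or H1047R) to 2324 alike (without the third E545K library). The interaction ranged from 786 (without the third MCF7 MUT library) to 9938 (without the third E545K library). It called 786 to 1088 without one MCF7 library, 1046 to 1226 without one WT-labelled MCF10A library, and 1065 and 1052 without the first and second E545K libraries. Lists ranged from 9 to 10 in MCF7, 13 to 16 for E545K, 12 to 16 for H1047R, 6 (without the third E545K library) to 16 between the mutants, and 11 to 17 in the interaction.

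Mean log2 fold changes of 5 lists turned between H1047R and E545K without the third E545K library: the mitochondrially encoded respiratory chain to 0.10, MYC targets to -0.16, NF-kB and cytokines to -0.44, basal markers to -0.04 and ribosomal proteins to -0.04. Without the third library of both groups MYC targets were at -0.18, NF-kB and cytokines at -0.92, basal markers at -0.13 and ribosomal proteins at -0.10. Over the libraries left out in turn these means ranged from -1.13 to 0.10 (respiratory chain), -0.16 to 0.35 (MYC), -0.46 to 0.43 (NF-kB, lowest without the third H1047R library, where it was not called), -0.04 to 0.90 (basal) and -0.04 to 0.32 (ribosomal).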

Other observations

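The tests and genes in this part were all chosen after the values were seen. In MCF7, neighbouring genes moved together beyond chromosome 18 in 5-Mb windows with at least 10 genes. At 50 to 55 Mb on chromosome 18, where 6 of 14 genes had 0 counts in WT, the median log2 fold change of MUT over WT was 7.56 with these genes at their bound. Other medians were 1.76 at 35 to 40 Mb on chromosome 18, -1.02 at 50 to 55 Mb on chromosome 22, -0.82 at 105 to 110 Mb on chromosome 14 1.06 at 115 to 120 Mb on chromosome 1, and 1.27 at 100 to 105 Mb and 1.16 at 120 to 125 Mb on chromosome X. Windows from 175 to 190 Mb on chromosome 3, the first of which holds PIK3CA, had medians of 0.80, 0.56 and 0.72. Of 459 windows, 30 had a median of at least 0.5 in either direction.

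In MCF10A, a stretch around ERBB2 on 17q, from SRCIN1 to PSMD3 (38530016 to 39997960), parted the libraries labelled WT from those labelled H1047R. Each of its genes with at least 5 CPM in a library stood higher in the WT-labelled libraries, CDK12 the least at 6.69-fold. ERBB2 stood 106-fold higher, GRB7 80.6-fold, MIEN1 46.1-fold, STARD3 42.4-fold, PSMB3 17.8-fold and RPL19 14.3-fold. Beyond PSMD3 the ratios of WT to H1047R went both ways. They were 0.000199 for CSF3, 0.279 for MED24, 0.52 for TOP2A, 1.05 for WIPF2 and 1.13 for MSL1, but 42.0 for THRA and 2150 for IGFBP4. The third E545K library had the WT-labelled level of ERBB2 (396 CPM). The basal keratin KRT14 parted the third H1047R library from both mutant groups, at 11707 CPM between 333 to 446 CPM in the other H1047R libraries and 24208 to 26295 CPM in the first 2 E545K libraries.

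The second pattern is that the third library of each MCF10A mutant group stands with another group. A wrong label on the third libraries may account for it: the lowest Spearman coefficient of the third E545K library with a WT-labelled library was 0.982, against 0.981 for the least similar WT-labelled pair. A swap between 2 groups of the table is argued against, since 0 WT-labelled or E545K libraries sat in the place of a misplaced one. A mixture of cells of 2 groups is argued against by the genes scored, since the higher of the median shares of the other cells' transcripts was 1.17%, where 5% was needed. For the third H1047R library these were 18 genes higher in H1047R than in E545K. Genes higher in E545K were not scored, so a mixture is not settled for that library. Its KRT5, at 3066 CPM, lay between the other H1047R libraries (1904 and 2135 CPM) and the first 2 E545K libraries (6836 and 6317 CPM), as did its KRT14. The KRT14 level of the third H1047R library leaves open whether it is an E545K library, and other markers went both ways. Its KRT17, at 12472 CPM, lay with the other H1047R libraries (11474 and 15560 CPM) and apart from the first 2 E545K libraries (24206 and 21901 CPM). Its VIM, at 67.0 CPM, lay nearer those E545K libraries (69.1 and 82.0 CPM) than the other H1047R libraries (46.9 and 42.1 CPM).

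The third pattern is that the MCF10A libraries labelled WT hold luminal and not basal transcripts. Cells of another line in these libraries may account for it: 836 genes were off on one side against the first 2 H1047R libraries, 12.3 times the 68 between the MCF7 groups, and CDKN2A, which MCF10A lacks, was counted in each. RNA of MCF7 cells is argued against, since 13.2% of the abundant transcripts that part them (10 of 76) were below 1 CPM in MCF7, where at most 5% was allowed. A response of one isogenic line to the PIK3CA mutations stays open on ERBB2 and KRT8 alone, because the 1 library of 6 labelled with a mutation that keeps their level may itself carry a wrong label. CDKN2A argues against it for the WT-labelled libraries, since an MCF10A line that lacks the gene would not transcribe it. Each of them held at least 289 counts, against 0 in the H1047R libraries and the first 2 E545K libraries. Until the cells are typed, the comparisons with WT-labelled MCF10A libraries do not measure effects of the mutations alone.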
